A study of Mus musculus with 4 samples.

How the data were processed

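Single-cell RNA sequencing on the 10x Chromium system was done on cells of the tracheas of 2 adult mice, each sorted by FACS into a GFP-positive, donor-derived library and a GFP-negative, endogenous library within a Calcein Blue live gate, per the labels' protocols. The deposited matrices hold UMI counts per gene and cell barcode. Per the submitters' processing notes, Cell Ranger, STARsolo and Seurat were used with the build GRCm38; the notes give no versions and do not say which tool made the counts. The deposited gene list holds 30907 features, and a reporter feature for EGFP was part of it, per the file headers. No barcode had a low total (the lowest totals were 2910 to 4296 UMIs per library), so the deposited barcodes had already been reduced to cells; the rule behind this is not stated. The deposited counts were used as they were.

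Of the 30907 gene IDs, 30843 were found in the GENCODE vM21 annotation of the same build, from which positions were taken. For 127 features whose deposited symbol was shared with another feature, the name belonging to the gene ID was used. Of 677 genes on the lists, 4 had no match by symbol (Rian, Best4, Dnai1 and Dnai2) and were not analysed here. Whether counting used the strand is not stated. Reads of overlapping or antisense genes, and of near-identical copies, can therefore be shared. This holds for Airn and Igf2r, Kcnq1ot1 and Kcnq1, Zrsr1 and Commd1, and for Spag6l, Ftl1-ps1, BC018473 and Rpl29, and also among the Ly6, Hspa1, Cyp2a, Cyp4a, Sult1, Ugt2b, Serpina3, Fmo and H2 families; their values are uncertain in that respect.

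The cell filter, markers, gene lists, comparisons and the rule for naming genes were fixed before the data were examined. Barcodes with fewer than 500 detected genes or more than 20% mitochondrial UMIs were removed. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5 and removed; they made up 2.96% and 1.38% of barcodes in the endogenous and donor-derived libraries of the iBC recipient, and 1.06% and 0.59% in those of the primary BC recipient. The 4 libraries were then clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used, with sex-linked and reporter features kept out of the variable genes. Leiden clustering (leidenalg 0.10.2) at resolution 1.0 gave 26 clusters, counting subclusters made at resolution 0.5 where unrelated classes each reached a score of 2. Each cluster was compared with the other cells of the same libraries, with a prior of 20 CPM. It was called X-like when the mean log2 enrichment of a class's markers reached 1, at least 3 of them were 2-fold higher, and its top 10 genes held no more markers of another class than of its own. Those scoring limits were set with the data at hand. Clusters that failed them stayed unnamed.

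UMIs were summed per class and library and scaled to CPM of the class sum. Ratios were computed as log2 of CPM plus a pseudocount of 5 CPM. Folds are ratios of CPM without pseudocount. Classes with at least 50 cells in both libraries of a comparison were compared. Because each group had 1 library, no test was made and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals, and CPM values and ratios carry exact Poisson 95% intervals; both cover counting error only, not differences between animals or libraries. Where a count was 0, the limit that 3 counts allow is given, and folds against it are lower bounds over the class sum.

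The named genes were, per comparison and class, the 5 highest and 5 lowest log2 ratios among genes with at least 50 CPM and 50 UMIs in either class sum. They also had to differ at least 2-fold, with the interval bound nearest to 1 at least 1.5-fold away. Cell type markers, sex-linked and reporter features, genes without a symbol of their own, and genes whose CPM was under 10% of that in another named class of the library were left out of this ranking. A ciliated-like gene that the rule names in the primary BC recipient is not reported here. Gene lists were summarised by the median log2 ratio of members with at least 20 CPM in either class sum. Its percentile among 10000 random lists of the same size, matched on mean expression within 100 ranks, describes these libraries and is not a test. Members at least 1.5-fold apart, with an interval excluding 1, were counted as higher or lower. A list with fewer than 3 measured members was given no value. Similarity was Pearson's r of log2 values across genes with at least 10 CPM in either sum; genes are not independent replicates.

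The calculation was tested on simulated data drawn from the real class sums with 200 changed genes per comparison and class. The draws were Poisson counts, the model behind the intervals, without variation between cells or libraries. The rates below check the calculation and do not give the error in the real data. In the basal-like, secretory-like and ciliated-like classes, 98.0% to 100.0% of 2-fold changes and 100.0% of 4-fold changes were called in the right direction. In the hillock-like class of the primary BC recipient, where 6350 genes entered, 87.0% of 2-fold changes were called. False calls were highest there as well, at 2.68% of 6150 unchanged genes, against 0.36% of 6347 in the ciliated-like class of the same recipient.

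Alternatives were no cell filter, a filter at 1000 genes and 10% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2.0, and separate clustering of each library. For expression they were TMM (edgeR 4.0.16 in R 4.3.3) and median-of-ratios scaling, the mean of per-cell CPM, thinning of every cell to 2000 UMIs, a pseudocount of 1 CPM, and no filter on low genes. A further pair, chosen after seeing the data, left differing marker genes out of the clustering. Other software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A control trachea that the protocol mentions was not analysed here.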

Results

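The airway epithelium of the mouse trachea is kept up by basal cells, which give rise to secretory and ciliated cells. Cells were profiled from the tracheas of 2 recipient mice. Their epithelium had been injured with 2% polidocanol, a detergent, and 6000000 cells were placed in the trachea 5 hours later. The first animal received primary basal cells (BCs) and was examined after 69 days; its libraries carry the strain label C57BL/6. The second received basal cells made from embryonic stem cells in culture (iBCs) and was examined after 192 days; its libraries carry the label 129 X1/S1. GFP marked cells descended from the transplant. Each trachea gave a donor-derived library and an endogenous library, so each of the 4 groups held 1 library from 1 animal, and no value has a replicate. Donor cell kind, days, strain and animal differed together between the recipients.

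The 4 libraries held 6784 barcodes, of which 6520 cells were kept. In the iBC recipient the endogenous library had 21813234 UMIs and 1795 kept cells, and the donor-derived library 21504563 UMIs and 1563 kept cells. In the primary BC recipient the endogenous library had 24808125 UMIs and 1354 kept cells, and the donor-derived library 26625123 UMIs and 1808 kept cells. Median UMIs per barcode ran from 9298 in the endogenous library of the iBC recipient to 14175 in that of the primary BC recipient. The EGFP reporter had 65.4 CPM in the donor-derived library of the iBC recipient and 611 CPM in that of the primary BC recipient, against 0.0971 and 8.04 CPM in the matching endogenous libraries.

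The first question was which epithelial cell types the transplanted cells had formed. Basal-like, secretory-like and ciliated-like cells were found in both donor-derived libraries. Basal-like cells made up 35.3% (95% interval 32.9 to 37.7) of donor-derived cells in the iBC recipient and 43.5% (41.2 to 45.8) in the primary BC recipient. Endogenous cells were basal-like in 48.8% (46.4 to 51.1) and 33.2% (30.7 to 35.7) of cases. Secretory-like cells were 31.7% (29.4 to 34.1) of donor-derived and 27.9% (25.79 to 29.99) of endogenous cells in the iBC recipient. In the primary BC recipient they were 13.4% (11.85 to 15.04) of donor-derived and 19.5% (17.4 to 21.7) of endogenous cells. Ciliated-like cells were 16.6% (14.8 to 18.6) and 20.1% (18.23 to 21.98) of donor-derived and endogenous cells in the iBC recipient, and 8.85% (7.58 to 10.3) and 14.1% (12.3 to 16.1) in the primary BC recipient. Different clusters held these classes in different libraries, and the basal-like and secretory-like shares moved with the clustering. No difference between groups is drawn from them.

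**Figure D1:**
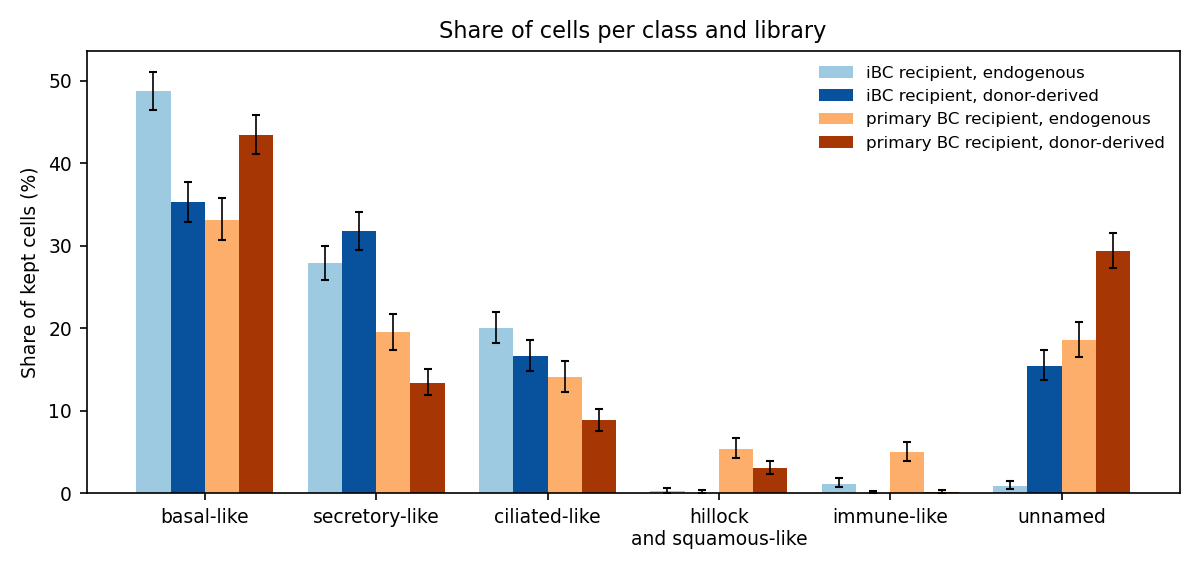
Share of kept cells (%) in each class for the 4 libraries; bars are shares and error bars exact 95% binomial intervals, which cover counting error only. Basal-like cells run from 33.2% to 48.8%, and unnamed cells reach 29.4% in the donor-derived library of the primary BC recipient.

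Rarer types were few. Hillock-like cells, a squamous-like state with Krt13 and Krt4, made up 5.39% of endogenous and 3.04% of donor-derived cells in the primary BC recipient. They were 0.22% and 0.06% in the iBC recipient. These shares depend on naming, since the unnamed clusters 13 and 17 also carried hillock genes such as Krt13 and Krt4. Of donor-derived cells, tuft-like cells made up 0.06% in the iBC recipient and 0.28% in the primary BC recipient, ionocyte-like cells 0.13% and 0.5%, deuterosomal-like cells 0.06% and 0.5%, and cycling-like cells 0.58% and 0.28%. Neuroendocrine-like cells were 0 of 1563 donor-derived cells in the iBC recipient, which allows up to 0.192%, and 0.22% in the primary BC recipient. Immune-like cells were 1.17% and 4.95% of the endogenous cells of the iBC and primary BC recipients. Among donor-derived cells they were 0 of 1563, which allows up to 0.192%, and 0.11%. The GFP sort may set this contrast, which was not tested. In the endogenous library of the primary BC recipient, 4 of 67 immune-like cells had a UMI of the reporter. Fibroblast-like cells were not seen in either donor-derived library, with limits of 0.192% and 0.166%.

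Unnamed clusters held 15.5% of donor-derived and 0.89% of endogenous cells in the iBC recipient, and 29.4% and 18.5% in the primary BC recipient. Cluster 15, led by Fmo6, Hpgd and Hes1, held 22.8% of donor-derived and 16.3% of endogenous cells of the primary BC recipient. Cluster 17, led by S100g, Ces1f and Krt4, held 6.08% and 1.92%. Cluster 13, led by Krt13, Upk3bl and Sfn, held 7.36% of the donor-derived cells of the iBC recipient. Cluster 7, led by Ccl20 and Ccl9, held 5.82% of them, and cluster 2.0, with Pir and Aox3 among its leading genes, 2.3%. No other library had more than 9 cells in any of the last 3 clusters. A cluster mostly of 1 library may be that library, not a type.

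How closely donor-derived cells resembled their endogenous neighbours was asked next, within each animal. In the primary BC recipient, 99.9% of donor-derived cells lay in clusters where at least 10% of the cells of that recipient were endogenous. Cluster 8, with 290 donor-derived and 33 endogenous cells, lay just above that limit. In the iBC recipient the share was 2.05%. Among the 15 nearest neighbours of donor-derived cells within the same recipient, 21.8% were endogenous in the primary BC recipient, against 42.8% under full mixing. In the iBC recipient the value was 1.59% against 53.5%.

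Class sums gave the same order. Across genes, Pearson's r between donor-derived and endogenous cells of the primary BC recipient was 0.983 for basal-like, 0.984 for secretory-like and 0.982 for ciliated-like cells, and 0.953 for the smaller hillock-like class. In the iBC recipient r was 0.914, 0.882 and 0.906. Endogenous cells of the 2 recipients, which differ in strain label, days and animal, gave 0.958, 0.945 and 0.938. Donor-derived cells of the 2 recipients gave 0.882, 0.834 and 0.87. Each donor-derived class of the iBC recipient was nonetheless closer to the same endogenous class than to another. Its basal-like cells had r of 0.914 with endogenous basal-like cells, 0.737 with endogenous secretory-like and 0.489 with endogenous ciliated-like cells. Classes were named from the same markers in all libraries, which favours this order, so it is no separate test of cell identity.

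**Figure D2:**
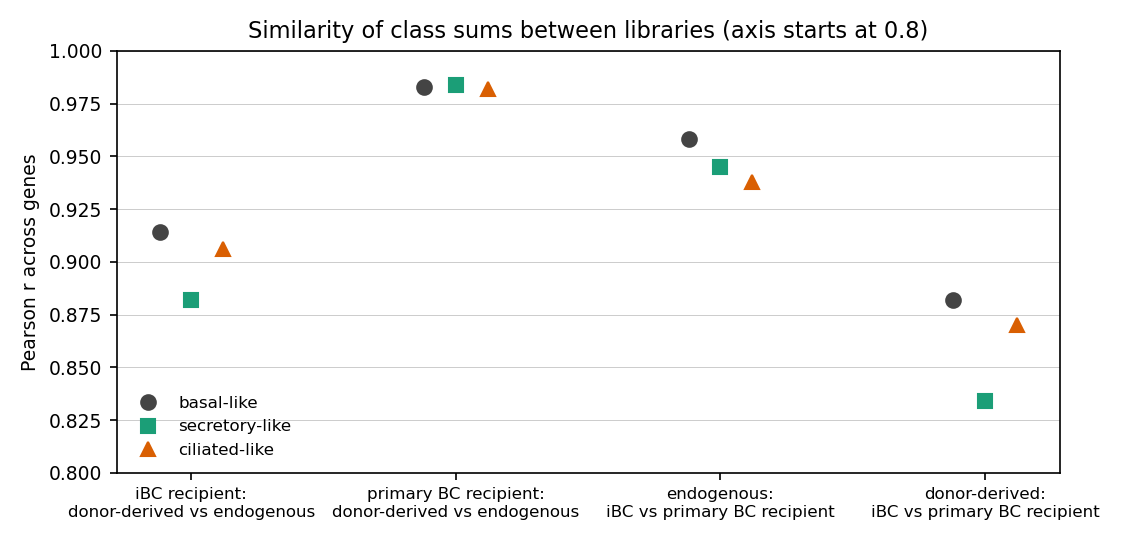
Pearson's r across genes of log2(CPM + 5) between class sums for 4 pairs of libraries, with a symbol per class; the axis starts at 0.8. Donor-derived and endogenous cells of the primary BC recipient lie at 0.982 to 0.984, and those of the iBC recipient at 0.882 to 0.914, below the endogenous pair at 0.938 to 0.958.

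Within the iBC recipient, the next comparison asked how cells derived from iBCs differed from endogenous cells of the same class, animal, day and digestion. In all 3 classes the MHC class II genes were higher, and the acute phase and antimicrobial, xenobiotic, mitochondrially encoded and regional transcription factor lists had medians below that of all genes. Cdkn2a was high in donor-derived and nearly absent from endogenous cells. The median of all genes was shifted by 0.12, 0.43 and 0.09 (log2) in basal-like, secretory-like and ciliated-like cells. TMM scaling brought these shifts to -0.01, 0.02 and -0.01. Medians of lists are therefore given relative to the shift. Counts of members higher or lower use folds without that correction unless said otherwise. In secretory-like cells, with a shift of 0.43, this favours higher over lower members. The median absolute log2 ratio about it was 0.184, 0.21 and 0.24. Clusters 3 and 4 held the endogenous basal-like cells and cluster 18 the donor-derived ones. Clusters 1 and 12 held secretory-like, and clusters 0 and 16 ciliated-like cells. The unnamed clusters 7 and 13 scored highest for basal markers, at 0.75 and 1.3, and held 91 and 115 donor-derived cells of this recipient. Those cells are outside the basal-like sum, so the mix of cells was not excluded for basal-like differences.

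Genes of antigen presentation were higher in donor-derived cells of the iBC recipient. All 6 measured MHC class II members were higher in each class, with medians of 2.24 in basal-like, 2.58 in secretory-like and 2.75 in ciliated-like cells, above the middle 95% of random lists. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, protein coding) had 2222 CPM in donor-derived and 375 CPM in endogenous basal-like cells. In secretory-like cells it had 2009 and 200 CPM, and in ciliated-like cells 1625 and 184 CPM. A UMI of Cd74 was found in 87.5% of donor-derived and 37.6% of endogenous basal-like cells, at median depths of 8393 and 7869 UMIs; in endogenous ciliated-like cells of the primary BC recipient the share was 8.4% at 18754 UMIs. H2-Eb1 rose from 15.4 to 484 CPM in secretory-like cells. MHC class I medians were 0.34, 0.63 and 0.75, with 7 of 15, 7 of 14 and 9 of 15 members higher and 1, 0 and 0 lower. B2m went from 723 to 1585 CPM in basal-like cells, while H2-Q6 fell from 41.0 to 13.1 CPM. Interferon-stimulated genes as a list stayed near the shift, at -0.2, 0.17 and 0.01.

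Host defence and detoxification genes were lower. The acute phase and antimicrobial list had medians of -1.7, -2.17 and -1.55, with 8, 8 and 6 of 9 members lower and 1, 0 and 2 higher. Several members, such as Reg3g and Bpifa1, were also on the secretory marker list. In basal-like cells Reg3g fell from 601 to 8.73 CPM. A UMI of Bpifa1 was found in 56.9% of endogenous and 1.15% of donor-derived ciliated-like cells. RNA of secretory-like cells was therefore not excluded for the basal-like and ciliated-like medians. Among members not on that marker list, Wfdc2 fell from 4069 to 1772 CPM in basal-like cells, and C3 from 470 to 137 CPM in secretory-like cells. In ciliated-like cells C3 rose from 9.99 to 72.7 CPM and Lcn2 from 29.0 to 148 CPM; a UMI of C3 was found in 35.4% of donor-derived and 8.06% of endogenous ciliated-like cells, at median depths of 11844 and 11853 UMIs. Xenobiotic and glutathione genes had medians of -0.66, -0.36 and -0.7, with 14 of 23, 11 of 24 and 12 of 23 members lower, and 0, 2 and 1 higher. Cyp2a5 fell from 360 to 0.728 CPM in basal-like cells, where 4 UMIs remained, and from 2650 to 85.3 CPM in secretory-like cells. Its basal-like values go with those of secretory markers, as Scgb3a1 fell from 778 to 11.3 CPM in basal-like cells, so RNA of other cell types in endogenous basal-like cells was not excluded. Cyp2b10 went the other way in secretory-like cells, from 31.0 to 190 CPM. Mitochondrially encoded genes had medians of -0.4, -0.34 and -0.68, with 4, 2 and 8 of 13 members lower relative to the shift and 0 higher, whereas nuclear oxidative phosphorylation genes lay at -0.14, -0.01 and 0.03.

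Regional transcription factors had medians of -1.14, -0.48 and -0.42, with 10 of 16, 6 of 13 and 5 of 13 members lower, and 3, 4 and 3 higher. In basal-like cells Irx1 had 1.27 CPM in donor-derived and 41.0 CPM in endogenous cells, and Tbx1 had 0.728 and 35.9 CPM. Irx2 was lower in secretory-like cells at 3.88 against 39.5 CPM. Gata6 was higher in ciliated-like cells at 70.9 against 4.65 CPM. The TGF-beta and BMP target list had a median of 1.12 in ciliated-like cells, with 3 of 5 members higher and 0 lower, and Id1 went from 15.1 to 200 CPM. That list stood at 0.22 in basal-like cells, with 3 of 7 members higher and 2 lower, and at 0.31 in secretory-like cells, with 2 of 4 higher and 0 lower.

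The remaining lists moved less or differently by class. Immediate early genes had medians of -0.18, 0.42 and 0.24, and senescence and DNA damage genes 0.24, 0.19 and 0.36. Imprinted genes had medians of 0.54, 0.11 and -0.38, with members moving both ways. Cholesterol and fatty acid synthesis was at -0.76 in secretory-like cells, with 8 of 11 members lower, and at -0.11 and 0.02 in the other classes. Notch pathway genes were at 0.18, -0.33 and 0.23, YAP targets at 0.07, -0.01 and -0.39, and ion transport genes at -0.3, 0.01 and 0.03. Wnt targets were at 0.01, 0.38 and 0.47. In basal-like cells Lgr6 fell from 63.5 to 1.45 CPM and Wnt4 rose from 500 to 933 CPM. Hemidesmosome genes were at -0.04, 0.42 and -0.3, and keratins at -0.55, 0.34 and -0.05. Heat shock genes were at -0.26, -0.07 and 0.06, and chemokines at -1.07 and 0.55 in basal-like and secretory-like cells. The donor-derived basal-like sum lacks the unnamed cluster 7, led by Ccl20 and Ccl9, which limits its chemokine median. The basal-like keratin and heat shock medians and the secretory-like chemokine and Wnt medians changed sign under an alternative. The cilium axoneme list was at -0.26 in ciliated-like cells, with 7 of 24 members lower and 0 higher. Tekt1 had 11.4 against 331 CPM, while Foxj1, the regulator of ciliogenesis, had 663 and 723 CPM. Cell cycle genes had too few measured members.

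**Figure D3:**
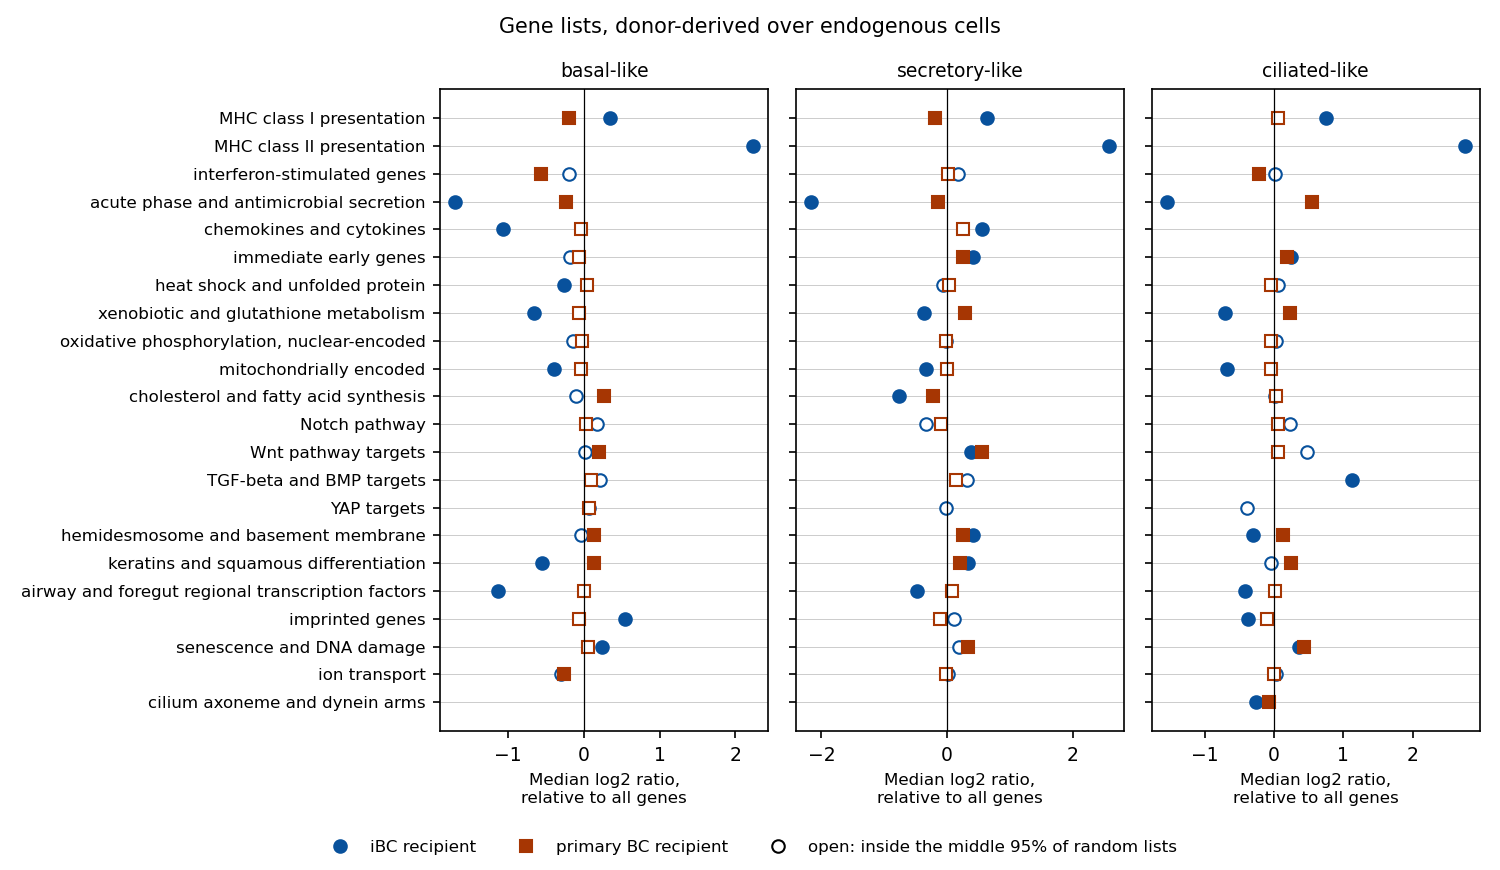
Median log2 ratio of each gene list, donor-derived over endogenous cells, relative to the median of all genes, in 3 classes; circles are the iBC recipient, squares the primary BC recipient, and filled symbols lie outside the middle 95% of random lists. MHC class II presentation lies at 2.24 to 2.75 and the acute phase list at -2.17 to -1.55 in the iBC recipient.

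By the fixed rule, the basal-like genes with the lowest ratios were Ly6k, Sult1d1, Msln, Hspb1 and Fmo6. Sult1d1 (ENSMUSG00000029273, chromosome 5, 87554645 to 87569027, protein coding) had 67.3 CPM in donor-derived and 1416 CPM in endogenous cells, a 21.0-fold difference (18.97 to 23.4). Hspb1 had 22.4 and 509 CPM. The highest were Cryab, Cdkn2a, Rapgef5, Filip1l and Foxq1. Cryab had 107 CPM against 1.24 CPM, 86.3-fold higher (45.2 to 190). Cdkn2a, with 56.9 CPM against 0 UMIs, was at least 138-fold higher. In secretory-like cells Ly6k, Sult1d1, Slc16a11, Cd36 and Hspb1 were lowest and Fabp5, Cryab, Clu, Areg and H2-Eb1 highest. Slc16a11 had 0.969 against 221 CPM, and Clu 2358 against 67.0 CPM, 35.2-fold higher (32.3 to 38.3). Ly6k rested on 2 UMIs in donor-derived cells, and its ratio had an interval of 374-fold to 11180-fold lower. In ciliated-like cells Muc16, Spag16, Slc16a11, Spag6l and Drc1 were lowest, and Cdkn2a, Cacna1s, Foxq1, Id3 and Olfm4 highest. Muc16 had 16.3 against 748 CPM and Spag16 4.96 against 265 CPM, 53.4-fold lower (33.2 to 92.0). Foxq1 had 200 against 7.43 CPM. Olfm4 rested on 2 UMIs in endogenous cells, with an interval of 30.7-fold to 936-fold higher.

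Within the primary BC recipient, the same comparison was made for descendants of cells taken from a trachea. Here the donor-derived and endogenous cells of a class mostly shared clusters: cluster 19 for secretory-like, 20 for ciliated-like and 6 for hillock-like cells. Basal-like cells fell into cluster 9 (493 donor-derived and 402 endogenous cells) and cluster 8 (290 and 33). All-gene shifts were 0.03, 0.05, -0.03 and, for hillock-like cells, 0.07. Median absolute log2 ratios about them were 0.099, 0.107, 0.118 and 0.206. Most list medians lay within 0.3 of the shift.

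Interferon-stimulated genes were lower in donor-derived basal-like and hillock-like cells of the primary BC recipient, with medians of -0.57 and -0.59. In basal-like cells 8 of 13 members were lower and 0 higher, and in hillock-like cells 5 of 11 were lower and 0 higher. Ifi27l2a fell from 432 to 111 CPM and Isg15 from 51.7 to 21.8 CPM in basal-like cells. The list was not examined inside cluster 9 alone, so the different mix of clusters 8 and 9 was not excluded for basal-like cells. In secretory-like and ciliated-like cells the list stood at 0.02 and -0.22. MHC class I medians were -0.2, -0.19, 0.06 and, in hillock-like cells, 0.37. MHC class II had too few measured members. The acute phase list was at -0.24, -0.15, 0.54 and -0.87; the hillock-like MHC class I and acute phase values changed sign under alternatives. Chil4 rose from 43.6 to 737 CPM in secretory-like cells. The ciliated-like value rested on few cells: 10 of 160 donor-derived cells held 95.9% of the Bpifa1 UMIs and 93.6% of those of Ltf. The same 10-cell share was 92.2% for Krt15 and 98.0% for Krt5, so the keratin median of 0.25 in this class is limited in the same way.

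Xenobiotic genes were at -0.06, 0.28, 0.23 and -0.18 over basal-like, secretory-like, ciliated-like and hillock-like cells. In the same order, senescence and DNA damage genes were at 0.06, 0.33, 0.43 and 0.13, immediate early genes at -0.06, 0.26, 0.19 and -0.22, and cholesterol genes at 0.26, -0.23, 0.03 and 0.2. Hemidesmosome genes were at 0.14, 0.26, 0.13 and 0.05, and ion transport genes at -0.26, -0.01, 0 and -0.37. Wnt targets were at 0.2, 0.55, 0.05 and -0.26, and keratins in the other classes at 0.14, 0.21 and -0.1. The basal-like Wnt, keratin and hemidesmosome medians changed sign under alternatives, as did the hillock-like xenobiotic, cholesterol and imprinted gene medians. Chemokines were at -0.04, 0.25 and -0.12 without ciliated-like cells, TGF-beta and BMP targets at 0.09, 0.14 and 0.35 likewise, and YAP targets at 0.07 and 0.17 in basal-like and hillock-like cells. Notch genes were at 0.03, -0.09, 0.06 and 0.13, heat shock genes at 0.04, 0.03, -0.05 and -0.03, and regional transcription factors at 0, 0.07, 0.02 and 0.02. Imprinted genes were at -0.06, -0.11, -0.1 and -0.25, nuclear oxidative phosphorylation genes at -0.03, -0.02, -0.05 and -0.06, and mitochondrially encoded genes at -0.04, 0, -0.04 and -0.21. The cilium axoneme list was at -0.07 in ciliated-like cells and the cell cycle list at 0.07 in hillock-like cells.

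Apoe, Cd36, Apoc1, Mme and Trf had the lowest ratios among named genes in donor-derived basal-like cells of the primary BC recipient. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, protein coding) had 162 CPM in donor-derived and 1920 CPM in endogenous cells, 11.8-fold lower (11.2 to 12.5). Cd36 had 2.79 and 62.3 CPM, and Apoc1 40.4 and 265 CPM. Apoe and Apoc1 also rank among the leading genes of cluster 9. Inside cluster 9 alone, which was examined after the values were seen, Apoe was 11.0-fold lower (10.3 to 11.8) and Apoc1 5.02-fold lower (4.42 to 5.72). The highest ratios were those of Upk3bl, Ly6d, Lgals3, St6galnac2 and Sparc; Sparc had 167 against 76.2 CPM. Upk3bl, Ly6d and Lgals3 turned lower when cells were clustered without differing markers, whereas inside cluster 9 they were 2.97-fold (2.29 to 3.89), 1.68-fold (1.32 to 2.14) and 2.15-fold (1.98 to 2.34) higher. In secretory-like cells Lrg1, Ifi27l2a, Cldn10, Slc38a1 and Chil1 were lowest and Clic3, Cd81, Ly6d, Fmo1 and Timp3 highest. Lrg1 had 20.8 against 81.3 CPM and Clic3 52.15 against 15.02 CPM. In ciliated-like cells 4 genes passed on the lower side, Ctsk, Unc79, Cd36 and Gsn; Gsn had 326 against 664 CPM. The higher side included Cdkn2a, Calml3, Gcnt1 and Serpinb12. Calml3 had 281 against 54.6 CPM. Cdkn2a had 99.9 CPM against 1 UMI in endogenous cells, with an interval of 65.8-fold to 14640-fold higher.

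The last comparison within animals asked which changes the recipients shared. Across genes, the log2 ratios of the recipients had Pearson's r of 0.31 in basal-like, 0.325 in secretory-like and 0.011 in ciliated-like cells, and Spearman's rho of 0.172, 0.263 and -0.021. Among genes at least 2-fold apart in the same direction in both, Apoe was lower in basal-like cells, from 3548 to 647 CPM in the iBC recipient and from 1920 to 162 CPM in the primary BC recipient. Mme, Cd36 and Cbr2 were also lower and Ahnak2 higher in basal-like cells. Secretory markers were lower there as well, such as Scgb3a1 from 230 to 42.8 CPM in the primary BC recipient, so RNA of other cell types was not excluded for genes that secretory-like cells also express. In secretory-like cells Clic3 and Cd81 were higher and Lrg1 lower. Marker genes among the shared ones, Scgb3a1, Bpifb1, Gp2, Tff2 and Chad, were all lower in these cells. Scgb3a1 went from 97170 to 4775 CPM in the iBC recipient and from 48360 to 23170 CPM in the primary BC recipient. In the same order, Tff2 went from 2084 to 6.18 CPM and from 1523 to 329 CPM. In ciliated-like cells Gsn, Ctsk and Unc79 were lower and Cdkn2a higher. The secretory markers Scgb1a1 and Muc5b were higher there as well. Scgb1a1 went from 3923 to 19850 CPM in the iBC recipient and from 495 to 1809 CPM in the primary BC recipient. RNA of other cell types was thus not excluded in ciliated-like cells for genes that secretory-like cells also express.

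Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653, protein coding) encodes inhibitors of the cell cycle. Its donor-derived CPM in basal-like, secretory-like and ciliated-like cells was 56.9, 102 and 130 in the iBC recipient, and 14.4, 28.7 and 99.9 in the primary BC recipient. Endogenous CPM in these classes was at most 1.39. The share of cells with a UMI was 39.9%, 78.2% and 80.8% in donor-derived cells of the iBC recipient and 12.3%, 38.0% and 65.0% in those of the primary BC recipient. In endogenous cells of these classes it was at most 1.5%. Median depths were similar within a recipient, for example 8393 and 7869 UMIs in basal-like cells of the iBC recipient. After thinning to 2000 UMIs the donor-derived shares were 9.6%, 20.4% and 23.5%, and 2.7%, 8.3% and 16.2%, against at most 0.4% in endogenous cells. Cdkn2b, its neighbour (chromosome 4, 89306299 to 89311039), rose from 12.8 to 72.4 CPM in ciliated-like cells of the iBC recipient and from 14.1 to 46.1 CPM in those of the primary BC recipient.

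**Figure D4:**
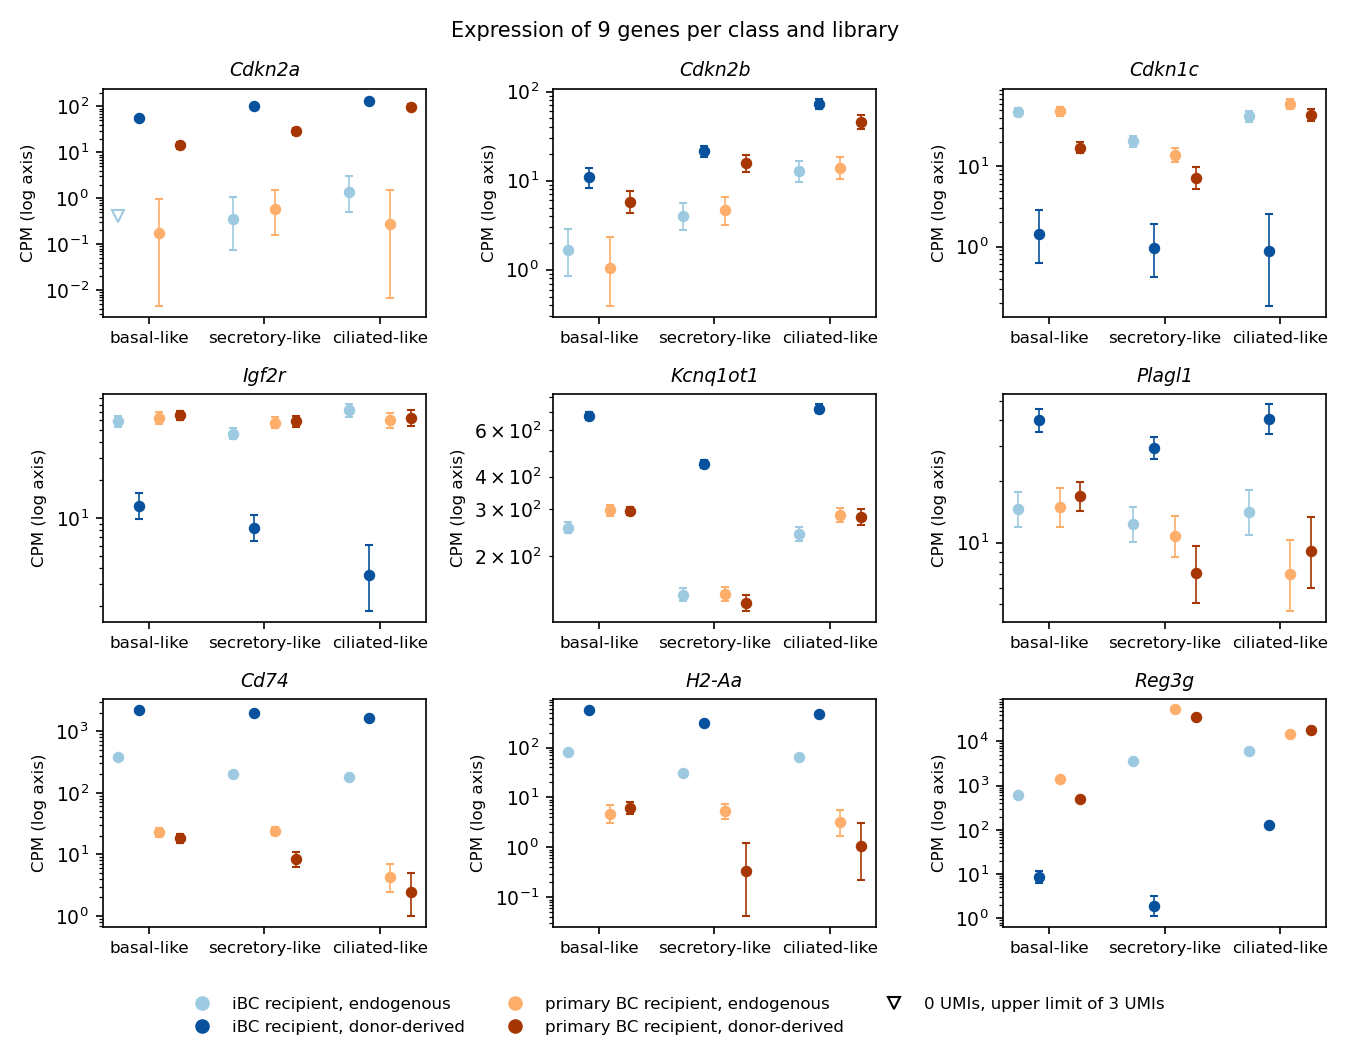
CPM of 9 genes (log axes) in 3 classes and 4 libraries; bars are exact 95% Poisson intervals, and open triangles mark 0 UMIs at the limit of 3 UMIs. Cdkn2a lies at 14.4 to 130 CPM in donor-derived cells and at or below 1.39 CPM in endogenous cells.

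Donor-derived cells were then compared between recipients, with the endogenous pair beside them as background for strain label, days and animal. That background covers strain only if the donor cells had the strain of their recipient, which cannot be told here. The shift of all genes in the donor pair was 0.05, 0.19 and 0.09, and in the endogenous pair -0.05, -0.21 and -0.03. Median absolute log2 ratios were 0.251, 0.296 and 0.269 in the donor pair and 0.175, 0.208 and 0.204 in the endogenous pair. The donor difference holds donor cell kind as well as strain, days and animal, which cannot be separated here.

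MHC class II genes were higher in the iBC recipient in both pairs. List medians were 5.45, 5.56 and 5.9 for donor-derived and 3.12, 2.01 and 2.87 for endogenous cells, over 6, 6 and 6 and over 4, 3 and 4 measured members. MHC class I showed 1.22, 0.93 and 1.32 in donor-derived and 0.67, 0.21 and 0.5 in endogenous cells. Medians of the heat shock list lay above those of all genes in both pairs, at 0.32, 0.71 and 0.73 against 0.5, 0.73 and 0.47. The acute phase list was at -1.89, -2.25 and -1.61 in donor-derived cells, against -0.02, -0.52 and 0.48 in endogenous cells, where the ciliated-like value changed sign under alternatives. The ciliated-like value of the donor pair includes the same 10 cells of the primary BC recipient that held 95.9% of its Bpifa1 UMIs. Xenobiotic genes were at -0.86, -0.65 and -0.47 against -0.24, -0.11 and 0.22. Regional transcription factors were at -1.13, -1.04 and -0.68 against -0.32, -0.17 and -0.2. Cholesterol synthesis in secretory-like cells was at -1.3 against -0.83.

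The named genes of the donor pair included MHC class II genes in all 3 classes. In basal-like cells Lgr6, Cdo1, Sult1d1, Abi3bp and Ugt2b34 were lowest in the iBC recipient, and Cd74, Ftl1-ps1, BC018473, H2-Eb1 and H2-Aa highest. Lgr6 (ENSMUSG00000042793, chromosome 1, 134983301 to 135105276, protein coding) had 1.45 against 150 CPM. In secretory-like cells Sult1d1, Cyp2a5, Slc16a11, Cyp4a12b and Clca1 were lowest, and Psca, Cd74, H2-Eb1, Ftl1-ps1 and Fabp5 highest. Psca had 794 CPM against 0 UMIs, at least 1537-fold higher, and Cyp4a12b had 0 UMIs against 233 CPM, at least 640-fold lower. In ciliated-like cells Serpinb11, Gtsf1l, Itln1, Serpina9 and Pttg1 were lowest, and BC018473, Cd74, H2-Ab1, H2-Aa and Ftl1-ps1 highest. Itln1 had 12.8 against 683 CPM.

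In the endogenous pair Rpl29 was among the lowest and Ftl1-ps1 among the highest in all 3 classes. In basal-like cells Apobec3, Smim6, Cald1 and Ang were also lower in the iBC recipient, and Ly6k, Ly6d, Serpina3n and H2-Q7 higher; Ly6d had 550 against 22.9 CPM. In secretory-like cells Ramp1, Dhrs9, Sema3d and Sult1b1 were lower, and BC018473, Ly6k, Hspa1a and Hspa1b higher; Ramp1 had 2.03 against 99.4 CPM. In ciliated-like cells Gtsf1l, Pttg1, Fanca and Serpina9 were lower, and BC018473, Prss30, AW112010 and Sptssb higher; Prss30 had 172 against 4.87 CPM. Of these, Ftl1-ps1, BC018473, Gtsf1l, Serpina9 and Pttg1 were also named in the donor pair, so those differences were present in both pairs. Genes not named there could differ in it too, as Ly6d had 2608 against 60.4 CPM in donor-derived basal-like cells.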

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

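All tests in this part were chosen after the results they examine had been seen. The contrast of donor-derived against endogenous cells drew attention wherever its direction was opposite in the 2 recipients. With 1 library per group these differences between recipients were not tested, and donor kind, days, strain and animal are confounded in them. The basal-like share was 13.5 percentage points lower in donor-derived than in endogenous cells of the iBC recipient (a difference of -13.5) and 10.31 points higher in those of the primary BC recipient. These signs depended on the clustering. In the iBC recipient the donor-derived share was the higher at Leiden resolution 2.0 (46.32% against 35.21%) and with doublets kept (49.53%, just above the endogenous share). For the primary BC recipient it was the lower with separate clustering (0.0% against 16.62%). There 60.01% of its donor-derived and 26.37% of its endogenous cells stayed unnamed. No cluster of that donor-derived library was named basal-like, so the 0.0% may reflect naming and not absence. No difference in composition is drawn from these shares. MHC class I presentation had median log2 ratios of 0.34 and -0.2 in basal-like cells, and of 0.63 and -0.19 in secretory-like cells, for the iBC and primary BC recipients; in the latter 0 of 11 members were 1.5-fold apart in either class. In the same order, acute phase and antimicrobial secretion in ciliated-like cells was at -1.55 and 0.54. Xenobiotic and glutathione metabolism was at -0.36 and 0.28 in secretory-like cells and at -0.7 and 0.23 in ciliated-like cells. Hemidesmosome and basement membrane genes in ciliated-like cells were at -0.3 and 0.13, with 0 of 10 and 0 of 9 members 1.5-fold apart, and keratins in basal-like cells at -0.55 and 0.14. Both keratin signs changed under alternatives, to 0.26 with separate clustering in the iBC recipient and to -0.17 at Leiden resolution 2.0 and -0.3 without differing markers in the primary BC recipient. Among named genes, Fmo1 had log2 ratios of -1.82 and 1.19 in secretory-like cells. In ciliated-like cells Calml3 had -3.28 and 2.26, and Serpinb12 -1.67 and 1.12.

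The counts behind the ciliated-like values differed in their spread over cells. A UMI of Calml3 was found in the primary BC recipient in 65.0% of donor-derived and 38.7% of endogenous ciliated-like cells, at median depths of 17192 and 18754 UMIs. The 10 donor-derived cells with most UMIs held 29.4% of those of Calml3. The acute phase median of 0.54 rested more on few cells, in which 10 of 160 donor-derived cells held 95.9% of the Bpifa1 UMIs, against 61.1% in 10 of 191 endogenous cells. In the iBC recipient, where the median was -1.55, 10 of 360 endogenous ciliated-like cells held 73.5% of the Bpifa1, 85.1% of the Ltf and 88.6% of the Bpifb1 UMIs. Whether those cells were uncalled doublets was not tested.

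The reporter was seen in data sorted to lack it. The endogenous library of the primary BC recipient held 191 EGFP UMIs in 29 of 1354 cells, of which 19 cells with more than 2 UMIs held 179. The endogenous library of the iBC recipient held 2 UMIs in 1 cell. Whether the 19 cells were donor-derived cells missed by the sort was not tested.

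Imprinted genes of the iBC recipient split by parental allele. With alleles assigned by hand after the values were seen, 16 of 17 values of paternally expressed members were higher in donor-derived cells, such as Kcnq1ot1 at 679 against 256 CPM in basal-like cells, and 7 of 8 values of maternally expressed members were lower, such as Igf2r at 12.6 against 58.8 CPM and Cdkn1c at 1.46 against 47.5 CPM; of 11 values of members whose allele depends on the tissue, 1 was higher, 3 were lower and 7 neither. These values repeat the same genes over the 3 classes and are not independent. Paternally expressed members were Kcnq1ot1, Plagl1, Sgce, Impact, Zrsr1 and Airn, and maternally expressed ones Igf2r, Cdkn1c and Slc22a18. Reads shared between overlapping transcripts were argued against, since 12 of 14 values of members without an overlapping gene followed the pattern. Those values came from Cdkn1c, Impact, Plagl1, Sgce and Slc22a18. Of the values of Kcnq1ot1 and Zrsr1, 0 of 6 had a partner moving the same way. Airn and Igf2r, which overlap each other, moved in opposite directions relative to all genes. The log2 values were 0.54 and -1.98 in basal-like, 0.88 and -2.39 in secretory-like, and 0.58 and -3.26 in ciliated-like cells. Shared reads would move both the same way, so these values argued against them as the source of the directions, while the sizes stay uncertain. Each value had to pass 1.5-fold relative to the median of all genes, so a shift of the class total had been taken out beforehand. Its size, at most 0.43 (log2) in the 3 classes, therefore gives no test of the pattern. A strain of the donor other than the recipient's cannot be told, since 2 of only 4 genes that separate the recipients 8-fold stayed within 2-fold between donor-derived and endogenous cells. BC018473 passed 2-fold in basal-like cells alone (1.44, log2), moving further from the level of the primary BC recipient. Ly6k moved toward that level, at -4.68, -5.99 and -4.29 in the 3 classes. Altered imprinting in the iBC donor cells may be a candidate explanation; in the primary BC recipient 0 of 4 paternal values were higher and 1 of 7 maternal values was lower, and the difference between recipients was not tested.

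Kdm5d, a gene on chromosome Y, was nearly absent from donor-derived cells of the iBC recipient, with 11 UMIs or 0.525 CPM (0.262 to 0.940) against 14.2 CPM in endogenous cells. Loss of the Y chromosome was argued against, since the lowest fold of Ddx3y, Eif2s3y and Uty was 0.931 (0.807 to 1.08). Depth was argued against, since 297 UMIs were expected at the endogenous level. A donor strain or line that differs from the recipient at Kdm5d could be a candidate explanation and cannot be told from the same 2 of 4 separating genes. No biological explanation was tested.

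Cdkn2a was found in donor-derived and hardly in endogenous cells of both recipients. In both donor-derived libraries ciliated-like cells held at least 3.03 (2.61 to 3.51) times the UMIs per cell of basal-like cells. This argued against free RNA as the source in ciliated-like cells. For basal-like cells the ratio cannot decide, since free RNA from ciliated-like cells would leave the same excess. Among donor-derived cells, 78.2% (74.3 to 81.8) of secretory-like and 39.9% (35.8 to 44.2) of basal-like cells of the iBC recipient had a UMI. In the primary BC recipient the shares were 38.0% (31.9 to 44.5) and 12.3% (10.1 to 14.8). Free RNA alone would give like shares, so these argued against it as the only source in secretory-like cells. Depth was argued against by 6 of 6 pairs of class and recipient whose shares of cells with a UMI stayed apart after thinning. A variant or mapping error at Cdkn2a alone was argued against by its neighbour Cdkn2b, which was at least 3.28-fold (2.36 to 4.61) higher in the 6 pairs. No biological explanation was tested; an effect of culture, of transplantation or of the reporter construct stays open.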

How the results depend on the processing

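The alternatives that left differing markers out of the clustering were chosen after seeing the data; all others were planned. No paired analysis was possible because each recipient gave 1 pair of libraries. Over all alternatives, 3084 of 3368 list medians stayed within 0.25 (log2), 256 moved (114 closer to 0 and 142 further from it) and 28 changed sign. Of 1427 values of named genes 1258 stayed within 0.25 or their counting interval, 164 moved (79 closer to 0 and 85 further) and 5 changed sign. Of 417 values of marker genes 361 stayed within 0.25 and 56 moved, 18 closer to 0 and 38 further. Similarity moved by more than 0.05 in 5 of 87 values, the median absolute log2 ratio by more than 1.5-fold in 10 of 165, and shares out of their binomial interval in 47 of 108. Values of the main analysis are given in parentheses; unless said otherwise, the cause of a change was not tested.

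Under each alternative that gave a value for both recipients, r between donor-derived and endogenous cells was lower in the iBC than in the primary BC recipient. It was 0.88 to 0.963 against 0.963 to 0.992 in basal-like, 0.835 to 0.949 against 0.923 to 0.992 in secretory-like, and 0.869 to 0.96 against 0.916 to 0.99 in ciliated-like cells. MHC class II medians of the iBC recipient stayed between 1.76 and 2.45, 1.41 and 2.81, and 2.22 and 2.84 in basal-like, secretory-like and ciliated-like cells. TMM scaling, median-of-ratios scaling and a pseudocount of 1 changed no sign. A change of scaling largely cancels by construction in list medians, r and the median absolute log2 ratio, so little could change there.

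Shares depended on clustering. At Leiden resolution 0.5 basal-like cells were 48.88% (35.25%) of donor-derived cells of the iBC recipient and secretory-like cells 16.1% (13.38%) of those of the primary BC recipient; no hillock-like cluster was named. At resolution 2.0 basal-like shares over iBC endogenous, iBC donor, primary endogenous and primary donor cells were 35.21% (48.75%), 46.32% (35.25%), 7.75% (33.16%) and 17.26% (43.47%), and secretory-like shares 16.82% (27.86%), 0.0% (31.73%), 16.69% (19.5%) and 10.45% (13.38%); primary endogenous hillock-like cells were 1.62% (5.39%). In basal-like cells of the primary BC recipient, Wnt targets changed to -0.19 (0.2), keratins to -0.17 (0.14), Lgals3 to -0.1 (1.12), Ly6d to -0.03 (1.23) and the median absolute log2 ratio to 0.171 (0.099). Senescence genes in basal-like cells of the endogenous pair changed to 0.01 (-0.21).

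With each library clustered separately, basal-like shares in the same order were 35.99%, 16.7%, 16.62% and 0.0%, secretory-like shares 12.7%, 8.57%, 9.16% and 8.68%, and hillock-like shares 0.0% (0.22%) for iBC endogenous, 7.61% for primary endogenous and 7.36% (3.04%) for primary donor cells. Unnamed cells made up 16.77%, 51.57%, 26.37% and 60.01% over the libraries in that order, so shares of 0.0% may reflect naming and not absence. In hillock-like cells of the primary BC recipient, MHC class I changed to -0.31 (0.37), cholesterol genes to -0.17 (0.2) and imprinted genes to 0.13 (-0.25). In basal-like cells of the iBC recipient heat shock genes changed to 0.15 (-0.26) and keratins to 0.26 (-0.55), and interferon-stimulated genes in basal-like cells of the endogenous pair to 0.31 (-0.4).

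Clustering without 42 of 218 markers gave basal-like shares of 38.32% for iBC donor, 19.65% for primary endogenous and 50.44% for primary donor cells, and a secretory-like share of 16.15% for primary donor cells. Of 449 primary endogenous basal-like cells 197 were among the 266 so named. In basal-like cells of the primary BC recipient Wnt targets changed to -0.07, hemidesmosome genes to -0.03 (0.14), keratins to -0.3, Lgals3 to -0.55, Ly6d to -1.54 and Upk3bl to -0.91 (1.42). The markers left out held all 10 of the secretory and 7 of the 10 basal markers. When they were left out of naming as well, no basal-like, secretory-like or hillock-like cluster could be named, and those results have no value.

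Without a cell filter, basal-like shares were 45.07%, 38.31%, 36.7% and 49.6%, secretory-like shares 30.19% for iBC endogenous and 17.21% for primary donor cells, and hillock-like shares 0.0%, 1.0% and 1.23% for iBC endogenous, primary endogenous and primary donor cells. Under the stricter filter basal-like shares were 52.97%, 41.43%, 27.57% and 34.7%, ciliated-like shares 16.74% (20.06%) for iBC endogenous and 12.04% (14.11%) for primary endogenous cells, secretory-like shares 14.37% and 10.46% for primary endogenous and donor cells, and the primary donor hillock-like share 4.4%. Wnt targets in basal-like cells of the primary BC recipient changed to -0.03, and acute phase and xenobiotic genes in its hillock-like cells to 0.09 (-0.87) and 0.09 (-0.18).

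With doublets kept, shares were 49.53% for iBC donor basal-like, 15.61% for primary donor secretory-like and 4.18% for primary donor hillock-like cells. Acute phase genes changed to -1.42 (0.48) in ciliated-like cells of the endogenous pair and to 0.07 in hillock-like cells of the primary BC recipient, where xenobiotic genes changed to 0.06. In basal-like cells of the donor pair chemokines changed to 0.31 (-0.56) and keratins to 0.1 (-0.51).

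With the mean of per-cell CPM, imprinted genes in ciliated-like cells of the donor pair changed to -0.07 (0.44). Without a filter on low genes, r in the iBC recipient rose to 0.96 (0.906) in ciliated-like and 0.949 (0.882) in secretory-like cells, and the median absolute log2 ratio of secretory-like cells of the donor pair was 0.195 (0.296); undetected genes enter with equal values by construction. In secretory-like cells Wnt targets changed to 0.16 (-0.5) in the endogenous pair and to -0.06 (0.38) in the iBC recipient, and chemokines to -0.16 (0.55) in the iBC recipient.

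Depth limited the precision. After thinning to 2000 UMIs per cell, r in the primary BC recipient was 0.923 (0.984) in secretory-like, 0.916 (0.982) in ciliated-like and 0.764 (0.953) in hillock-like cells, and median absolute log2 ratios were 0.189 (0.099) in basal-like, 0.289 (0.107) in secretory-like, 0.31 (0.118) in ciliated-like and 0.554 (0.206) in hillock-like cells. They were 0.364 (0.24) in ciliated-like cells of the iBC recipient, 0.428 (0.269) in those of the donor pair, and 0.333 (0.204) and 0.327 (0.208) in ciliated-like and secretory-like cells of the endogenous pair. Wnt targets changed to -0.04 in basal-like cells of the primary BC recipient and to 0.16 in secretory-like cells of the endogenous pair, acute phase genes to -0.38 in ciliated-like cells of the endogenous pair, and cholesterol genes to -0.01 in hillock-like cells. Fewer counts per class widen ratios by construction.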

Other observations

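All values in this part were chosen for report after the data had been seen. The EGFP reporter was found in 47.9% (45.4 to 50.4) of donor-derived cells of the iBC recipient and in 98.9% (98.3 to 99.3) of those of the primary BC recipient, at median depths of 11986 and 11924 UMIs. In the endogenous libraries it was found in 0.06% and 2.14% of cells, at median depths of 9318 and 14465.5 UMIs. After thinning to 2000 UMIs the donor-derived shares were 12.9% and 65.3%. In the primary BC recipient the reporter was at 1263 CPM in ciliated-like and 482 CPM in basal-like donor-derived cells.

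Of the 1563 donor-derived cells of the iBC recipient, 20 (1.28%) lay in clusters held mostly by endogenous cells. They held 1 reporter UMI against 1368 elsewhere in the library, and 4 Kdm5d UMIs against 7 elsewhere. Whether these were endogenous cells carried over by the sort was not tested. In the other direction, 12 of 1795 endogenous cells (0.67%) lay in clusters held mostly by donor-derived cells. Bpifa1, at 32920 CPM in endogenous secretory-like cells of the iBC recipient, was at 217 CPM in donor-derived ones, where 2.0% of cells had a UMI against 96.4% of endogenous ones.

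UMIs of distal lung markers were found in donor-derived cells of the iBC recipient. Those of Sftpc in basal-like and secretory-like cells lay mostly in few cells, those of Ager less so. Cluster 12, with 495 donor-derived cells of this recipient, scored 1.76 for secretory and 1.21 for alveolar type 2 markers, its next class. Sftpc was at 208 CPM in basal-like and 290 CPM in secretory-like cells, where the 10 cells with most UMIs held 68.3% and 94.6% of them. A UMI was found in 23.2% of basal-like, 10.9% of secretory-like and 11.9% of ciliated-like cells, at median depths of 8393, 16056 and 11844 UMIs. In the secretory-like class this share was no higher than in ciliated-like cells, so outside a few cells free RNA was not excluded. In endogenous basal-like cells the share was 0.1% at 7869 UMIs. Ager was at 99.2 CPM in donor-derived and 0.239 CPM in endogenous secretory-like cells, with a UMI in 15.3% and 0.4% of cells. In donor-derived ciliated-like cells 3.08% had a UMI of Ager, and 10 secretory-like cells held 46.9% of the UMIs of that class. Sftpb was at 230 and 143 CPM in donor-derived and endogenous secretory-like cells. In the primary BC recipient Sftpc was seen in ciliated-like cells, at 90.8 CPM in endogenous and 55.2 CPM in donor-derived cells.

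Afp, a gene of endoderm and fetal liver, was at 22.6 CPM in donor-derived and 0.477 CPM in endogenous secretory-like cells of the iBC recipient, with a UMI in 27.4% and 0.8% of cells. In donor-derived ciliated-like cells 7.31% had a UMI of Afp, at a median depth of 11844 UMIs against 16056 in secretory-like cells. Of the genes of pluripotent cells, Pou5f1 reached at most 0.364 CPM in the basal-like, secretory-like and ciliated-like cells of the iBC recipient, and Nanog had 0 UMIs in them, which allows up to 0.875 CPM in donor-derived ciliated-like cells.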
